A study of Homo sapiens with 64 samples.

How the data were processed

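The values analysed were gene counts from the deposited table of the series, whose unit is a count of reads per Ensembl gene, with 1 column for each of 64 libraries. The values are whole numbers and the authors applied no normalization to them. Per the labels, reads were aligned to GRCh38 with GSNAP, and its version, the counting tool and the annotation release are not given in the sources used here. All 64 columns were matched to a library through the library code in the labels, with 0 columns left unmatched. The table holds 58302 genes, of which 57532 carry a gene name and 58039 occur in GENCODE 29, which was used only for names, gene types and positions. The deposited per-library files hold a second counting over the whole gene body, with 34539 genes that have a count. For 64 of 64 libraries the file of the library itself was the best match to its column, with a lowest correlation of 0.978. These counts entered only as an alternative, and the length and RPKM columns were not used.

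Groups were the cell line, treatment and time of the labels, with 2 libraries each. Replicate numbers follow the order of deposit, and nothing in the labels ties replicate 1 of a group to replicate 1 of another. No group held the same library under 2 names: the lowest dispersion between replicates was a chi-square of 3.13 per degree of freedom, where 1 is counting noise alone.

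Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the 32 groups, which left 20890, and libraries were scaled by TMM. A single quasi-likelihood fit held a mean for each of the 32 groups over all 64 libraries, with 32 residual degrees of freedom, a common dispersion of 0.0111 and 7.53 prior degrees of freedom. Every comparison was a contrast of these means, tested on 2 sides, with the Benjamini-Hochberg method over genes within the comparison and a threshold of 0.05. No covariate was used. Differences between lines, between times and of drug pairs from the sum of their parts on the log scale were tested as interactions. Levels are CPM, counts scaled to a common total, on TMM-scaled library sizes. The standard error printed with a log2 fold change is the size of that change divided by the square root of the F statistic of its test.

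Each of the 20 gene lists was written before the data were examined and tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, in 42 comparisons. Members past the threshold were counted with p adjusted over all genes and, apart from that, over the list alone. Of the listed genes, 23 of 24 were measured for cholesterol synthesis, 18 of 19 for MAPK output, 10 of 16 for secreted senescence factors, 15 of 18 for basal and mesenchymal genes and 10 of 19 for markers of other cell types, and every gene of the other lists. For the median fold change of a list, a member with 3 or fewer counts in a library of the comparison entered with these libraries set to 3 counts, so that genes near 0 did not set the median. Correlations between lines are Pearson values over all tested genes unless Spearman is named, and describe the data without a test.

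The rule for naming genes was written before the data were examined. A gene could be named if it was 1 of the 8 target genes (ESR1, PIK3CA, PIK3CB, CDK4, CDK6, CCND1, RB1 and PGR). It could also be among the 6 highest or 6 lowest fold changes of protein-coding genes past the threshold, for the lines in DMSO and for single agents and the triplet against DMSO. Such genes needed a mean of at least 5 CPM in 1 group and both libraries of a group above both of the other. For list members the limit was the 4 with the largest change past the threshold, or a member named elsewhere. For interactions and for the triplet against pairs it was the 5 highest and 5 lowest, without the condition on replicates.

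The comparisons, the test, the threshold, the lists and the alternatives of normalization, filter, test, fit and replicates were fixed before the data were examined. Alternatives were the size factors of DESeq2 in the same fit, no filter (each gene with a count), a stricter filter (at least 1 CPM in 50% of the libraries), and DESeq2 1.42.0 with the Wald test on the same genes. A fit over the 32 libraries of the same line or of the same time, camera with an estimated correlation, and leaving out each library in turn were also run. Every p given for a list with an estimated correlation is adjusted over the lists of its comparison. The 64 fits without a library kept the tested genes and the trended dispersion of the full fit and estimated the quasi-dispersions anew, so the lone library of the group is assumed to vary like the other groups. Chosen after the data were seen were the gene-body counts, the fit without S1 DMSO replicate 2 and S1 palbociclib replicate 1 at 96 h, and the comparison of inavolisib added to a single agent. Without those 2 libraries S1 palbociclib at 96 h is compared with DMSO as 1 library with 1, and both are assumed to vary like the other groups.

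Before the data were analysed the code was run on simulated counts, in which 20185 genes were tested. Changes were planted in 200 genes for inavolisib at 24 h in each line. A list of 30 other genes was planted at 1.5 times in parental cells. For inavolisib in parental cells at 24 h the code recovered 32.8%, 53.7% and 71.2% of genes planted at 1.5, 2 and 4 times. Of its calls, 4.1% were in genes that were not changed. For the interaction with the line it recovered 20.1%, 46.3% and 71.2%, with 3.5% of such calls. The planted list had an adjusted p of 2.1e-33, and 0 other lists were called. Simulated genes were drawn independently, with 1 spread per gene in all groups. The 0 therefore cannot show how often a list of correlated genes is called wrongly in the real data.

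Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads were not analysed, so alignment, isoforms, variants and the ESR1 mutation were left out, as were drug doses, viability and protein.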

Results

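The series measured messenger RNA in 64 libraries from MCF-7, a human breast cancer cell line that depends on the oestrogen receptor, and from MCF-7.S1 (S1 in the text), a derivative with a mutation in ESR1. Each line was grown for 24 h or 96 h with the vehicle DMSO, with inavolisib, giredestrant or palbociclib, with each pair of these drugs, or with all 3 of them. Inavolisib inhibits the alpha form of PI3 kinase, giredestrant is an oral drug that blocks the oestrogen receptor and promotes its degradation, and palbociclib inhibits the cell cycle kinases CDK4 and CDK6. These 2 lines, 8 treatments and 2 times make 32 groups of 2 libraries. Doses and the identity of the ESR1 mutation are not given in the sources used here. Nor do the sources say whether the 2 libraries of a group came from separate cultures. Each p therefore rests only on the spread between such libraries, pooled for each gene over all 32 groups. A group whose libraries differ more than most, such as S1 in DMSO at 96 h, is tested with this shared spread. Its p values may be too small. With 1 line of each kind, an effect of the mutation cannot be told from any other difference between the lines.

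The libraries were made from polyadenylated RNA with a strand-specific kit and read as single reads of 50 bases. Total counts ran from 18200000 to 337000000 per library with a median of 31400000, and 23437 to 30541 genes had a count in a library. Of 43674 genes with a count, 20890 passed the expression filter and were tested, and these held 99.97% of all counts. Across these genes, which are not independent replicates, log expression of the 2 libraries of a group correlated at 0.9701 to 0.9933 (median 0.9864). The lowest value belonged to S1 in DMSO at 96 h and the next, 0.9802, to S1 in palbociclib at 96 h. Replicate 2 of the former stood apart on principal component 5 (-51.5 against -10.8 for replicate 1). Which library of the latter is odd is open. After the values were seen all counts were recomputed without the former's replicate 2 and the latter's replicate 1, called the pair that stood apart. The 7 treatments of a line at a time share 2 DMSO libraries, so these comparisons are not independent. Fold changes are log2 values with a standard error (SE, n = 2 libraries per group).

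**Figure D1:**
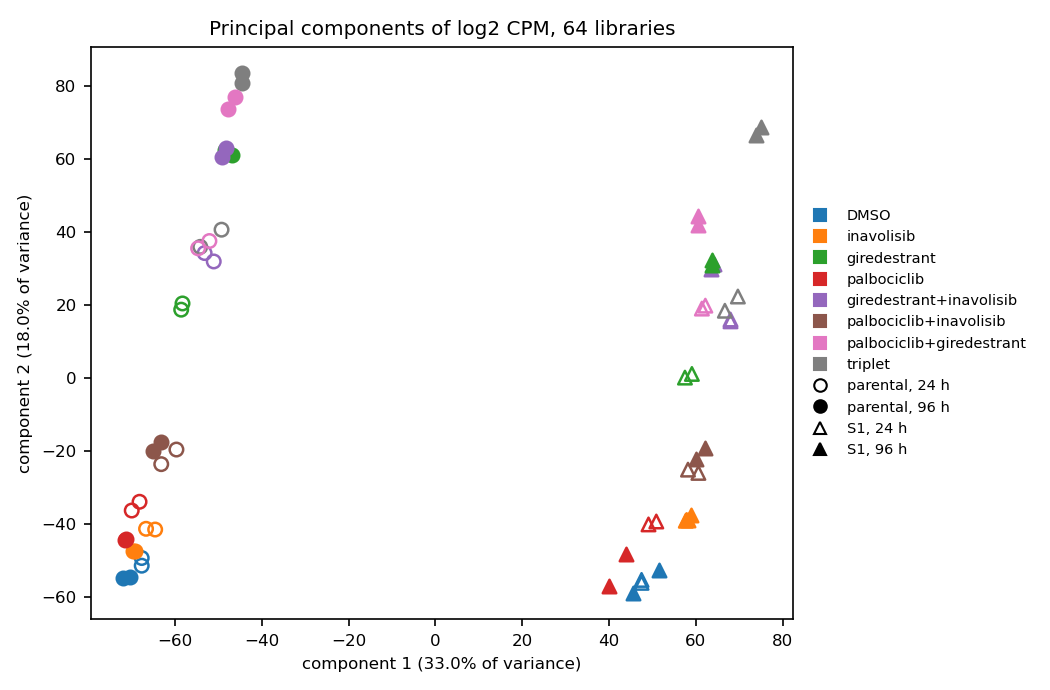
Principal components 1 and 2 of log2 CPM in 64 libraries, with colour for treatment, marker shape for cell line, open markers for 24 h and filled markers for 96 h. Component 1 holds 33% of the variance and separates the parental line from S1, and component 2 holds 18% and separates the groups with giredestrant from the others.

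ESR1 itself (ENSG00000091831, chromosome 6, 151656691 to 152129619 on GRCh38), which encodes oestrogen receptor alpha, was higher in S1 than in parental DMSO cells by 0.36 ± 0.09 at 24 h. Its level was 333 ± 11.7 against 260 ± 1.0 CPM (SD, n = 2). Giredestrant raised ESR1 in parental cells by 0.44 ± 0.09 at 24 h and 0.65 ± 0.09 at 96 h, whereas in S1 its values of 0.11 ± 0.09 and -0.01 ± 0.09 did not pass. The difference between the lines, S1 minus parental, was -0.34 ± 0.12 at 24 h (adjusted p = 0.165) and -0.66 ± 0.12 at 96 h (adjusted p = 0.000126). The 24 h difference passed in the fit over the same time (adjusted p = 0.0356) and without the pair that stood apart (0.0234). In S1 at 96 h ESR1 fell by 0.66 ± 0.09 with the triplet and by 0.59 ± 0.09 with palbociclib, the latter lost without the pair of libraries that stood apart (-0.30, adjusted p = 0.0574). PGR, the progesterone receptor gene and a classic oestrogen-induced transcript (ENSG00000082175, chromosome 11, 101029624 to 101130524), was higher in S1 by 0.74 ± 0.12 at 24 h, at 152 ± 0.323 against 91.0 ± 2.43 CPM. Giredestrant lowered PGR by 4.03 ± 0.15 and 5.36 ± 0.17 in parental cells at 24 h and 96 h and by 2.80 ± 0.13 and 4.44 ± 0.14 in S1. Its change with palbociclib did not pass in parental cells or S1 at either time. In S1 at 96 h it was lower with no filter (adjusted p = 0.0329), with the gene-body counts (0.0401), without DMSO replicate 1 (0.00104) or without palbociclib replicate 2 (0.0372). CDK6, a palbociclib target (ENSG00000105810, chromosome 7, 92604921 to 92836594), was higher in S1 by 2.04 ± 0.14 at 24 h. It rose with giredestrant by 1.31 ± 0.14 and 2.62 ± 0.14 in parental cells at 24 h and 96 h and by 1.33 ± 0.13 and 1.41 ± 0.13 in S1. CDK4, the other target (ENSG00000135446, chromosome 12, 57747727 to 57756013), fell with the triplet by 0.83 ± 0.06 in parental cells at 24 h and by 1.10 ± 0.06 in S1 at 96 h. CCND1, which encodes their partner cyclin D1 (ENSG00000110092, chromosome 11, 69641087 to 69654474), fell with giredestrant by 1.19 ± 0.08 and 1.30 ± 0.08 in parental cells and by 0.80 ± 0.08 and 1.47 ± 0.08 in S1. Between the lines in DMSO at 24 h the PI3 kinase subunit genes PIK3CA (ENSG00000121879, chromosome 3, 179148114 to 179240093) and PIK3CB (ENSG00000051382, chromosome 3, 138652699 to 138834938) did not pass (adjusted p = 0.127 and 0.143). In the fit over the same time both passed (-0.28, adjusted p = 0.0265, and 0.28, adjusted p = 0.00145). PIK3CB also passed with no filter (0.0252) and without the pair that stood apart (0.00498). RB1, the tumour suppressor that CDK4 and CDK6 phosphorylate (ENSG00000139687, chromosome 13, 48303726 to 48599436), was higher in S1 by 0.34 ± 0.12 at 24 h (adjusted p = 0.0276). This call was lost when replicate 1 or 2 of parental DMSO (0.36 and 0.31, adjusted p = 0.0717 and 0.131) or of S1 DMSO (0.33 and 0.30, adjusted p = 0.0877 and 0.135) was left out.

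The comparison of S1 with parental cells in DMSO shows how the lines differ without a drug. ROR2, a receptor for Wnt ligands, was higher in S1 by 6.10 ± 0.38 at 24 h, HOXD8, a homeobox transcription factor, by 5.90 ± 0.22 and FILIP1L by 4.76 ± 0.12. CALB2, which encodes the calcium-binding protein calretinin, was lower by 8.14 ± 0.45 and PCDH10, a protocadherin, by 7.90 ± 0.38. At 96 h ROR2 was higher by 6.75 ± 0.44, HOXD8 by 6.03 ± 0.23 and NTNG1, a netrin-like adhesion gene, by 5.31 ± 0.36, and FAT1, an atypical cadherin, was lower by 6.47 ± 0.50. Oestrogen-induced genes did not move as a block: 15 of 30 were higher and 9 lower at 24 h (16 and 9 adjusted over the list alone). TFF3, a secreted trefoil peptide, was higher by 3.73 ± 0.15 and the growth factor gene AREG (ENSG00000109321, chromosome 4, 74445134 to 74455009) lower by 3.34 ± 0.17. The list test gave adjusted p = 0.013, and adjusted p = 0.14 with an estimated correlation.

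Genes of amino acid supply and the ATF4 stress response were mostly higher in S1: 15 of 22 rose and 3 fell at 24 h (16 and 3 adjusted over the list alone; list adjusted p = 0.00027). PHGDH, which starts serine synthesis, was higher by 2.03 ± 0.11 and the stress-induced regulator NUPR1 by 2.14 ± 0.18. Mitosis genes were lower, 18 of 30 at 24 h with 0 higher (20 adjusted over the list alone) and 23 at 96 h (24 adjusted over the list alone). AURKB, a mitotic kinase (ENSG00000178999, chromosome 17, 8204733 to 8210600), was lower by 1.24 ± 0.11 at 24 h. Those calls, with adjusted p = 2.3e-06 and 7.4e-08, were lost with an estimated correlation (p = 0.14 and 0.098). Glycolysis and hypoxia genes were lower in 14 of 22 at 24 h (15 adjusted over the list alone, adjusted p = 3.7e-07), among them the aldolase gene ALDOC by 1.98 ± 0.11. Lysosome genes were lower in 14 of 20 (14 adjusted over the list alone, adjusted p = 1.3e-07), among them the hexosaminidase subunit HEXB by 1.26 ± 0.06. Cholesterol synthesis genes were lower in 12 of 23 (12 adjusted over the list alone, adjusted p = 0.00027), including SQLE, an oxidising enzyme of the pathway, by 1.38 ± 0.07. Of the 20890 genes, 8518 differed at 24 h (4182 higher in S1) and 9457 at 96 h (4684 higher). At 96 h the mitochondrially encoded list was lower in S1 (6 of 13 genes, adjusted p = 0.013). The call was lost without replicate 2 of S1 in DMSO (adjusted p = 0.888) and with an estimated correlation (p = 0.5).

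Inavolisib addresses what blocking PI3 kinase alone does. Genes that FOXO transcription factors induce when PI3 kinase signalling falls rose in both lines at 24 h, with 0 lower in either. They numbered 12 of 24 in parental cells (17 adjusted over the list alone, adjusted p = 9.4e-20) and 17 in S1 (19 adjusted over the list alone, adjusted p = 1.6e-18). PIK3IP1, a negative regulator of PI3 kinase, rose by 1.03 ± 0.10 in parental cells and 1.34 ± 0.10 in S1. IRS2, an adaptor of the insulin receptor (ENSG00000185950, chromosome 13, 109752698 to 109786568), rose by 0.87 ± 0.19 and 1.03 ± 0.18. At 96 h 6 members rose and 1 fell in parental cells (8 and 1 adjusted over the list alone, adjusted p = 6.8e-06). In S1 14 rose and 1 fell (14 and 1 adjusted over the list alone, adjusted p = 3.7e-09). SCD, which desaturates fatty acids, fell in all 4 settings, by 0.92 ± 0.08 and 1.03 ± 0.08 in parental cells and by 0.83 ± 0.08 and 1.36 ± 0.08 in S1 at 24 h and 96 h. Cholesterol synthesis genes fell in 17 of 23 in parental cells at 24 h (20 lower and 1 higher adjusted over the list alone, adjusted p = 3e-23) and in 12 in S1 (15 adjusted over the list alone, adjusted p = 3.2e-09).

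DNA replication genes fell at 24 h, and fewer of them were lower at 96 h. Of 36 E2F and replication genes, 29 fell in parental cells (34 adjusted over the list alone, adjusted p = 3.7e-37) and 36 in S1 (36 adjusted over the list alone, adjusted p = 1.8e-76). CDC45, part of the replicative helicase, was lower by 0.76 ± 0.10 and 1.47 ± 0.10. At 96 h 2 rose and 0 fell in parental cells (2 and 0 adjusted over the list alone, list higher with adjusted p = 0.0003). At that time 1 rose and 16 fell in S1 (2 and 17 adjusted over the list alone, adjusted p = 1.7e-05). Both 96 h calls were lost with an estimated correlation (p = 0.22 and 0.17), and without replicate 2 of parental DMSO the former had adjusted p = 0.0786. In S1 the amino acid and ATF4 list fell, 15 of 22 members at 24 h (16 adjusted over the list alone, adjusted p = 5.1e-52) and 17 at 96 h with 1 higher (18 and 1 adjusted over the list alone, adjusted p = 8e-29). In parental cells 6 fell and 0 rose at 24 h (8 and 0 adjusted over the list alone, adjusted p = 2.4e-07), and at 96 h 2 fell and 3 rose (2 and 3, adjusted p = 0.227, but lower with 0.0325 without DMSO replicate 1). In S1 CHAC1, a glutathione-degrading enzyme (ENSG00000128965, chromosome 15, 40952962 to 40956519), fell by 3.47 ± 0.26 and 2.64 ± 0.22, and SLC7A11, the cystine transporter (ENSG00000151012, chromosome 4, 138164097 to 138242349), by 3.98 ± 0.36 at 24 h. The other genes with large changes included the autophagy gene GABARAPL1, higher by 1.93 ± 0.21 in S1 at 24 h and the lipocalin APOD, higher by 1.76 ± 0.15 in parental cells at 96 h. CAV1, a membrane coat protein, was higher by 2.04 ± 0.11 in S1 at 96 h, and ETV5, a transcription factor downstream of MAPK, lower by 3.35 ± 0.37. The mitochondrially encoded transcripts were higher in S1 at 96 h (5 of 13, 7 adjusted over the list alone, adjusted p = 4.8e-06). The call was lost with an estimated correlation (p = 0.24) and without replicate 2 of S1 DMSO at 96 h (adjusted p = 0.894).

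In parental cells inavolisib changed 1754 genes at 24 h (673 higher) and 1118 at 96 h (479 higher), and in S1 3095 (1347 higher) and 4878 (2269 higher). Leaving out 1 library gave 684 and 1026 (DMSO replicates 1 and 2) and 821 and 874 (inavolisib replicates 1 and 2) in parental cells at 24 h. At 96 h it gave 607 and 579 (DMSO) and 490 and 498 (inavolisib). In S1 it gave 1876 and 2037 (DMSO replicates 1 and 2) and 1825 (inavolisib replicate 2) at 24 h, and 3097 (DMSO replicate 2) and 2500 (inavolisib replicate 1) at 96 h.

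Giredestrant addresses what blocking the oestrogen receptor alone does, and in both lines it lowered most oestrogen-induced genes. Of 30 oestrogen-induced genes, 30 fell in parental cells at 24 h and 28 at 96 h (30 and 28 adjusted over the list alone). In S1 29 fell at 24 h and 28 fell with 1 higher at 96 h (29, and 28 with 1 higher, adjusted over the list alone). The list's median log2 fold change was -2.01 and -2.88 in parental cells and -1.89 and -2.67 in S1 (adjusted p = 3e-114, 3.1e-78, 1.5e-127 and 6.4e-113). PDZK1, a scaffold protein of membrane transporters (ENSG00000174827, chromosome 1, 145670852 to 145708148), fell by 6.01 ± 0.36 in parental cells at 24 h, AREG by 4.36 ± 0.20 there and by 4.77 ± 0.28 in S1. GREB1, a cofactor of the receptor, fell by 5.54 ± 0.16 in parental cells and by 5.93 ± 0.16 in S1 at 96 h, and TFF1 by 5.61 ± 0.16 in S1. Oestrogen-repressed genes rose in 11 of 14 with 2 lower in parental cells at 24 h and in 12 with 1 lower at 96 h (the same counts adjusted over the list alone, adjusted p = 4.3e-19 and 1.6e-19). In S1 they rose in 10 with 2 lower and 9 with 2 lower (11 with 2, and 9 with 2, adjusted over the list alone; adjusted p = 2.7e-15 and 1.2e-18). PSCA, a surface antigen (ENSG00000167653, chromosome 8, 142670308 to 142682724), rose by 3.18 ± 0.21 and 4.92 ± 0.22 in parental cells and by 3.20 ± 0.21 and 4.99 ± 0.20 in S1.

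Among the largest changes, WNT11, a Wnt ligand (ENSG00000085741, chromosome 11, 76186325 to 76210736), rose by 3.75 ± 0.35 and 6.96 ± 0.35 in S1. Acetylcholinesterase, ACHE, rose by 3.48 ± 0.20 and 5.30 ± 0.22 in parental cells, while MGP, the matrix Gla protein, fell by 8.57 ± 0.65 in parental cells at 96 h. E2F and replication genes fell in 35 and 34 of 36 in parental cells at 24 h and 96 h, with 1 higher at 96 h, and in 34 and 29 in S1, with 1 higher at 96 h. Adjusted over the list alone the lower counts were 35, 34, 34 and 32, with 1 higher in all but S1 at 24 h, and the list's adjusted p was 5.2e-94, 5.8e-27, 2e-46 and 1.1e-15. Mitosis genes fell in 24 of 30 at 24 h and in 30 at 96 h in parental cells, and in 24 and 21 in S1 (27, 30, 25 and 22 adjusted over the list alone). In S1 at 96 h that call (adjusted p = 9e-08) was lost with an estimated correlation (p = 0.12). MYC, a growth regulator, fell by 1.45 ± 0.10 in parental cells and by 2.41 ± 0.11 in S1 at 24 h. Ribosome biogenesis genes fell with it, in 22 of 23 in parental cells at 24 h (22 adjusted over the list alone, adjusted p = 9.7e-18) and 13 in S1 (15 adjusted over the list alone, adjusted p = 3.9e-08). Cholesterol synthesis genes fell in 18 of 23 with 1 higher in parental cells at 24 h (18 and 2 adjusted over the list alone, adjusted p = 2.5e-13). Interferon and antigen presentation genes rose in 23 of 28 with 2 lower in parental cells at 96 h (23 and 2 adjusted over the list alone, adjusted p = 3.9e-10; 0.062 as the p with an estimated correlation). The poly-ADP-ribosyltransferase gene PARP9 rose by 2.04 ± 0.15. In S1 the amino acid and ATF4 list fell in 16 of 22 with 1 higher at both times (17 and 1 adjusted over the list alone, adjusted p = 8.1e-29 and 2.2e-18). SLC7A5, an amino acid transporter, was lower by 2.06 ± 0.10 and 3.07 ± 0.11 there. In parental cells 10 members fell and 3 rose at 24 h (11 and 3 adjusted over the list alone, adjusted p = 0.000105), and 10 fell and 5 rose at 96 h (10 and 6, adjusted p = 0.0334). The 96 h call was lost with an estimated correlation (p = 0.113) and without DMSO replicate 2 (adjusted p = 0.0701) or giredestrant replicate 1 (0.0929). The mitochondrially encoded list was higher in S1 at 96 h (12 of 13, 12 adjusted over the list alone, adjusted p = 0.00026). It was lost with an estimated correlation (p = 0.36) and without replicate 2 of S1 DMSO (adjusted p = 0.278).

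In parental cells giredestrant changed 4851 genes at 24 h (2258 higher) and 7993 at 96 h (4083 higher), and in S1 3826 (1930 higher) and 6839 (3264 higher). Without replicate 2 of S1 giredestrant at 24 h the count there was 2381.

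Palbociclib addresses what blocking CDK4 and CDK6 alone does, and fewer cell cycle genes were lower at 96 h than at 24 h. At 24 h 35 of 36 E2F and replication genes fell in parental cells and 36 in S1 (35 and 36 adjusted over the list alone, adjusted p = 9.9e-216 and 2.3e-160), with list medians of -1.85 and -1.50. RRM2, a subunit of ribonucleotide reductase (ENSG00000171848, chromosome 2, 10120698 to 10131419), fell by 2.86 ± 0.15 and 3.11 ± 0.16. Mitosis genes fell in 29 of 30 in parental cells and 30 in S1 (30 in each adjusted over the list alone, adjusted p = 1.8e-137 and 2.4e-164). AURKB was lower by 2.16 ± 0.12 and 2.59 ± 0.12. At 96 h 4 E2F and replication genes fell and 1 rose in parental cells (6 and 1 adjusted over the list alone), with a median of -0.17. For S1 14 fell and 1 rose (14 and 3 adjusted over the list alone), with a median of -0.20. Their adjusted p was 0.0044 and 0.0013, lost with an estimated correlation (p = 0.33 and 0.28), without replicate 1 of parental DMSO (0.235) and, in S1, without DMSO replicate 1 (0.0988) or palbociclib replicate 2 (0.08). Mitosis genes still fell in 19 of 30 at 96 h in parental cells (26 adjusted over the list alone, adjusted p = 2.3e-18), with CCNA2, cyclin A2, lower by 0.75 ± 0.11. In S1 at 96 h 5 mitosis genes fell and 2 rose (5 and 2 adjusted over the list alone) and the list did not pass (adjusted p = 0.76). Without DMSO replicate 2 there the mitosis list was lower with adjusted p = 0.012, and without DMSO replicate 1 it was higher with 0.0259.

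In S1 the amino acid and ATF4 list fell with palbociclib too, in 15 of 22 at 24 h and 18 at 96 h (16 and 18 adjusted over the list alone, adjusted p = 7.1e-44 and 3e-44). CHAC1 was lower by 2.73 ± 0.23 and NUPR1 by 2.30 ± 0.19 at 96 h. In parental cells 8 fell and 1 rose at 24 h and 7 fell and 1 rose at 96 h (9 and 1 at each time adjusted over the list alone, adjusted p = 2.5e-05 and 4.9e-07). PHGDH was lower by 1.30 ± 0.11 and 1.0 ± 0.11. At 96 h KRT7, an epithelial keratin, and BCAS1 rose in S1, by 1.35 ± 0.24 and 1.56 ± 0.08. The secreted protease gene ADAMTS9 rose by 1.89 ± 0.23 and the stress cytokine gene GDF15 fell by 0.85 ± 0.11 in parental cells. The mitochondrially encoded list was higher in S1 at 96 h (11 of 13, 13 adjusted over the list alone, adjusted p = 2.5e-09), which was lost with an estimated correlation (p = 0.22). In parental cells palbociclib changed 1904 genes at 24 h (548 higher) and 1796 at 96 h (809 higher), and in S1 2088 (1022 higher) and 4686 (2123 higher). Leaving out 1 library gave 1086, 1203 and 871 in parental cells at 24 h (DMSO replicates 1 and 2, palbociclib replicate 2). At 96 h it gave 829, 1054, 1135 and 840 (DMSO replicates 1 and 2, palbociclib replicates 1 and 2). In S1 it gave 1247, 1195, 1187 and 1194 at 24 h in the same order, and 7631, 1342 and 1375 at 96 h (DMSO replicates 1 and 2, palbociclib replicate 1). Without the pair of libraries that stood apart 998 genes changed there, in a comparison of 1 library with 1 that takes the spread from the other groups.

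With drugs in pairs, most mitosis genes were lower at 96 h. Palbociclib with inavolisib lowered 33 of 36 E2F and replication genes in parental cells at 96 h and 34 in S1 (33 and 34 adjusted over the list alone, adjusted p = 1.2e-34 and 1.1e-67), with medians of -0.89 and -1.45. It lowered 30 and 29 of 30 mitosis genes (30 and 29 adjusted over the list alone, adjusted p = 4.5e-66 and 5.2e-79). Palbociclib with giredestrant took the mitosis list to a median of -3.38 in parental cells, with 30 of 30 lower, and to -1.40 in S1, with 29 lower (30 and 29 adjusted over the list alone, adjusted p = 3.4e-94 and 1.3e-30). Giredestrant with inavolisib lowered 30 mitosis genes in parental cells and 22 in S1 (30 and 23 adjusted over the list alone, adjusted p = 9.7e-43 and 5.5e-08), and the S1 call was lost with an estimated correlation (p = 0.13). That pair differed from giredestrant alone in 0 and 5 genes at 96 h, so whether these changes include an effect of inavolisib is open. The mitochondrially encoded list was called higher in S1 at 96 h with palbociclib and inavolisib (13 of 13, 13 adjusted over the list alone, adjusted p = 7.4e-06). With giredestrant and inavolisib 4 rose (4 adjusted over the list alone, adjusted p = 0.0064), with palbociclib and giredestrant 4 (4, adjusted p = 0.0114), and with the triplet 5 (5, adjusted p = 0.0254). These 4 calls were lost with an estimated correlation (p = 0.253, 0.508, 0.548 and 0.639) and without replicate 2 of S1 DMSO (adjusted p = 0.161, 0.852, 0.863 and 0.964). At 24 h giredestrant with inavolisib changed 7355 genes in parental cells (3649 higher) and 6842 in S1 (3342 higher). Palbociclib with inavolisib changed 4502 (2022 higher) and 5122 (2688 higher), and palbociclib with giredestrant 6584 (3337 higher) and 5442 (2873 higher). At 96 h the counts in the same order were 7878 (3998 higher) and 7024 (3330 higher), 5192 (2620 higher) and 6458 (3337 higher), and 9193 (4868 higher) and 7606 (3713 higher). The count for palbociclib with inavolisib in parental cells at 24 h was 2915 without DMSO replicate 1 and 2692 without replicate 2 of the pair.

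**Figure D2:**
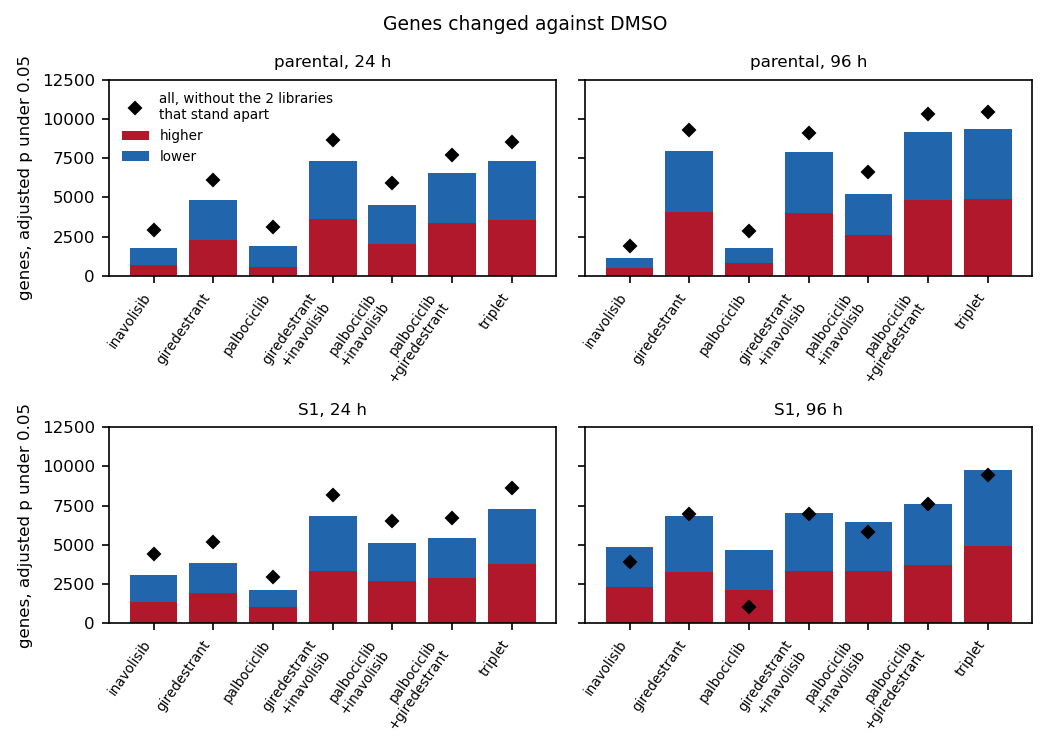
Genes that changed against DMSO at an adjusted p under 0.05, by treatment, in 4 panels for line and time, with bars split into higher and lower genes. Diamonds give the count without the 2 libraries that stood apart. The triplet changed 9773 genes in S1 at 96 h and inavolisib 1118 in parental cells at 96 h.

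**Figure D3:**
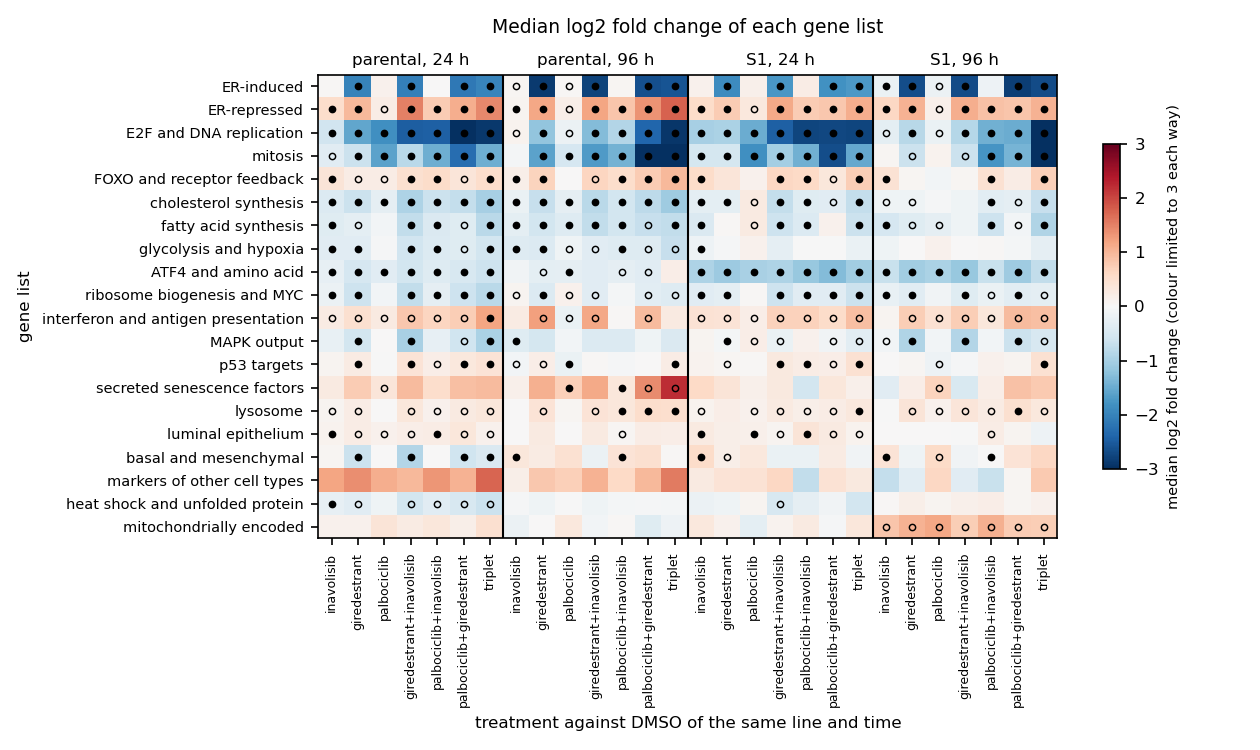
Median log2 fold change of each of 20 gene lists in each comparison of a treatment with DMSO, as colour limited to 3 on either side of 0. A filled dot marks a list call that held with an estimated correlation and an open dot a call made with the preset correlation alone. Oestrogen-induced genes were lower in every treatment with giredestrant, and the triplet lowered mitosis genes most, to -5.17 in S1 at 96 h.

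The triplet shows what all 3 drugs do together. At 96 h it lowered 30 of 30 mitosis genes in each line (30 in each adjusted over the list alone), with medians of -4.48 in parental cells and -5.17 in S1 (adjusted p = 1.6e-114 and 2.2e-119). AURKB fell by 5.10 ± 0.14 and 7.35 ± 0.18, CCNA2 by 5.18 ± 0.15 and 7.06 ± 0.17, and RRM2 by 7.23 ± 0.21 in S1. At 24 h the mitosis medians were -1.47 and -1.54, with 29 genes lower in each line (30 in each adjusted over the list alone, adjusted p = 2.7e-37 and 1.1e-39). E2F and replication genes fell in 35 and 36 of 36 at 24 h and in 35 and 36 at 96 h (the same counts adjusted over the list alone), with medians between -2.75 and -3.0. The replication origin factor MCM10 was lower by 5.65 ± 0.25 in parental cells at 24 h. Oestrogen-induced genes fell in 30 of 30 at 24 h and 28 at 96 h in parental cells and in 30 at both times in S1 (30, 29, 30 and 30 adjusted over the list alone). FOXO-induced genes rose in 17 of 24 with 2 lower and 19 with 1 lower at 24 h, and in 19 with 4 lower and 15 with 3 lower at 96 h, in parental cells and S1 in turn. Adjusted over the list alone these were 17 with 2, 19 with 2, 19 with 4 and 15 with 3, and the list's adjusted p was 4.4e-08, 2.2e-10, 3.4e-09 and 0.00013. DEPP1, a FOXO target, rose by 4.90 ± 0.31 in parental cells at 24 h.

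Of 13 fatty acid synthesis genes, the triplet lowered 9 at both times in parental cells and 9 and 11 in S1, with 0 higher (10, 9, 10 and 11 adjusted over the list alone). The list's adjusted p was 1.1e-07, 1.56e-06, 5.63e-06 and 2.82e-06, and with an estimated correlation 0.00358, 0.0114, 0.0136 and 0.0127. SCD fell by 2.03 ± 0.08 and 2.71 ± 0.08 in parental cells and by 1.44 ± 0.08 and 2.85 ± 0.08 in S1. Cholesterol genes fell in 21 of 23 at both times in parental cells and in 22 and 17 in S1, with 1 higher in each (22, 22, 22 and 18 lower adjusted over the list alone; adjusted p = 5.1e-22, 5.6e-14, 1.9e-15 and 1e-07). The p53 target list rose, in 13 of 20 with 2 lower and 9 with 5 lower in parental cells at 24 h and 96 h and in 15 with 1 and 12 with 3 in S1 (14 with 2, 9 with 5, 15 with 1 and 13 with 3 adjusted over the list alone; adjusted p = 2.3e-05, 0.00073, 8.6e-06 and 0.00023). BTG2, an antiproliferative gene, was higher by 3.05 ± 0.09 in parental cells at 96 h. Lysosome genes rose in 15 of 20 with 2 lower in both lines at 96 h (15 and 2 adjusted over the list alone; adjusted p = 3e-06 in parental cells and 0.0038 in S1, where the p with an estimated correlation was 0.15). The autophagy receptor gene SQSTM1 was higher by 1.87 ± 0.06 and 1.26 ± 0.06. CYP1A1, a cytochrome P450 induced by the aryl hydrocarbon receptor (ENSG00000140465, chromosome 15, 74719542 to 74725610), rose by 7.0 ± 0.36 in parental cells at 96 h. The stress factor gene DDIT3 rose by 2.53 ± 0.21 there and by 2.07 ± 0.20 in S1. At 24 h the triplet changed 7345 genes in parental cells (3548 higher) and 7285 in S1 (3741 higher), and at 96 h 9369 (4889 higher) and 9773 (4900 higher).

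Each drug's part in the triplet was tested against the pair without it. Inavolisib added to palbociclib with giredestrant moved the mitosis genes in opposite directions at the 2 times. At 24 h 24 of 30 rose in parental cells and 28 in S1 (30 in each adjusted over the list alone, adjusted p = 6.3e-60 and 3.2e-66), with medians of 0.80 and 1.15. At 96 h 23 and 30 fell (26 and 30 adjusted over the list alone, adjusted p = 1.4e-51 and 5.6e-222), with medians of -1.0 and -3.69. AURKB fell by 5.23 ± 0.20 in S1 at 96 h, and CENPA, which marks centromeres, rose by 1.67 ± 0.17 there at 24 h. At 96 h E2F and replication genes fell in 24 of 36 in parental cells and 36 in S1 (27 and 36 adjusted over the list alone, adjusted p = 2e-31 and 6.1e-118). Giredestrant added to palbociclib with inavolisib lowered oestrogen-induced genes, 30 of 30 at both times in parental cells and 30 and 29 in S1 (30 throughout adjusted over the list alone). The receptor-modifying protein gene RAMP3 fell by 7.46 ± 0.20 in parental cells and by 6.39 ± 0.16 in S1 at 96 h. Adding giredestrant lowered 1 of 30 mitosis genes in parental cells and 0 in S1 at 24 h (1 and 0 adjusted over the list alone; list adjusted p = 0.66 and 0.16). At 96 h it lowered 30 of 30 in each line (30 adjusted over the list alone, adjusted p = 4.7e-108 and 2e-105). The S1 list at 24 h was lower without replicate 1 of the triplet (adjusted p = 0.0309). Palbociclib added to giredestrant with inavolisib lowered 22 and 15 of 30 mitosis genes at 24 h (27 and 28 adjusted over the list alone, adjusted p = 3.3e-98 and 9.8e-87). At 96 h they numbered 30 in each line (30 adjusted over the list alone, adjusted p = 6.8e-227 and 4.2e-229), and AURKB was lower by 6.29 ± 0.19 in S1. The reference pair differed from giredestrant alone in 0 and 5 genes at 96 h, so whether this step added palbociclib alone or inavolisib as well is open.

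Adding inavolisib changed 1188 genes in parental cells at 24 h (493 higher), 1497 at 96 h (534 higher), and in S1 2799 (1263 higher) and 4415 (1872 higher). Adding giredestrant changed 2976 (1468 higher), 6103 (3101 higher), 2224 (1054 higher) and 5933 (2773 higher), and adding palbociclib 130 (3 higher), 2599 (1092 higher), 96 (5 higher) and 5444 (2559 higher), in the same order. Leaving out replicate 1 or 2 of the triplet or replicate 1 or 2 of palbociclib with giredestrant, in that order, moved the inavolisib counts in parental cells to 593, 652, 447 and 689 at 24 h and to 837, 745, 848 and 850 at 96 h. In S1 the inavolisib count at 24 h became 1732 without replicate 2 of the triplet and 1808 and 1617 without replicates 1 and 2 of palbociclib with giredestrant. At 96 h it became 2891 without replicate 2 of that pair. The giredestrant count at 24 h became 1792 without replicate 1 of palbociclib with inavolisib and 1959 without replicate 2 of the triplet in parental cells. In S1 it was 1472 and 1342 without replicate 2 of that pair and replicate 1 of the triplet. The palbociclib count at 24 h became 85, 81 and 45 in parental cells (without replicate 1 of giredestrant with inavolisib and replicates 1 and 2 of the triplet). In S1 it became 52, 30 and 14 (without replicates 1 and 2 of that pair and replicate 2 of the triplet). In parental cells at 96 h it became 1641, 1694, 1660 and 1598 (replicates 1 and 2 of that pair, then of the triplet).

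After the values were seen, inavolisib was also tested as an addition to giredestrant or to palbociclib alone. At 96 h its addition to palbociclib changed 3143 genes in parental cells (1724 higher) and 5435 in S1 (2983 higher), but its addition to giredestrant changed 0 and 5 (1 higher) by edgeR. For the 0, 1236 genes had an unadjusted p under 0.05 and DESeq2 called 0, and for the 5 DESeq2 called 8. At 24 h the counts for giredestrant were 1125 in parental cells (493 higher) and 3233 in S1 (1293 higher), and for palbociclib 1491 (701 higher) and 3287 (1436 higher). Leaving out giredestrant replicates 1 and 2 gave 1 and 166 genes in parental cells at 96 h, and in S1 leaving out any of the 4 libraries gave 0 to 2. At 24 h with giredestrant it gave 460 and 608 (giredestrant replicates 1 and 2) and 447 (replicate 2 of the pair) in parental cells. The S1 counts were 2081 and 2060 (replicates 1 and 2 of the pair) and 2063 (giredestrant replicate 2). With palbociclib at 24 h it gave 356 (replicate 2 of the pair), 769 and 726 (palbociclib replicates 1 and 2) in parental cells. S1 gave 1995 (replicate 1 of the pair), 2002 and 1942 (palbociclib replicates 1 and 2). At 96 h with palbociclib it gave 1516 (replicate 1 of the pair) and 1693 (palbociclib replicate 2) in parental cells and 3126 (palbociclib replicate 1) in S1.

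**Figure D4:**
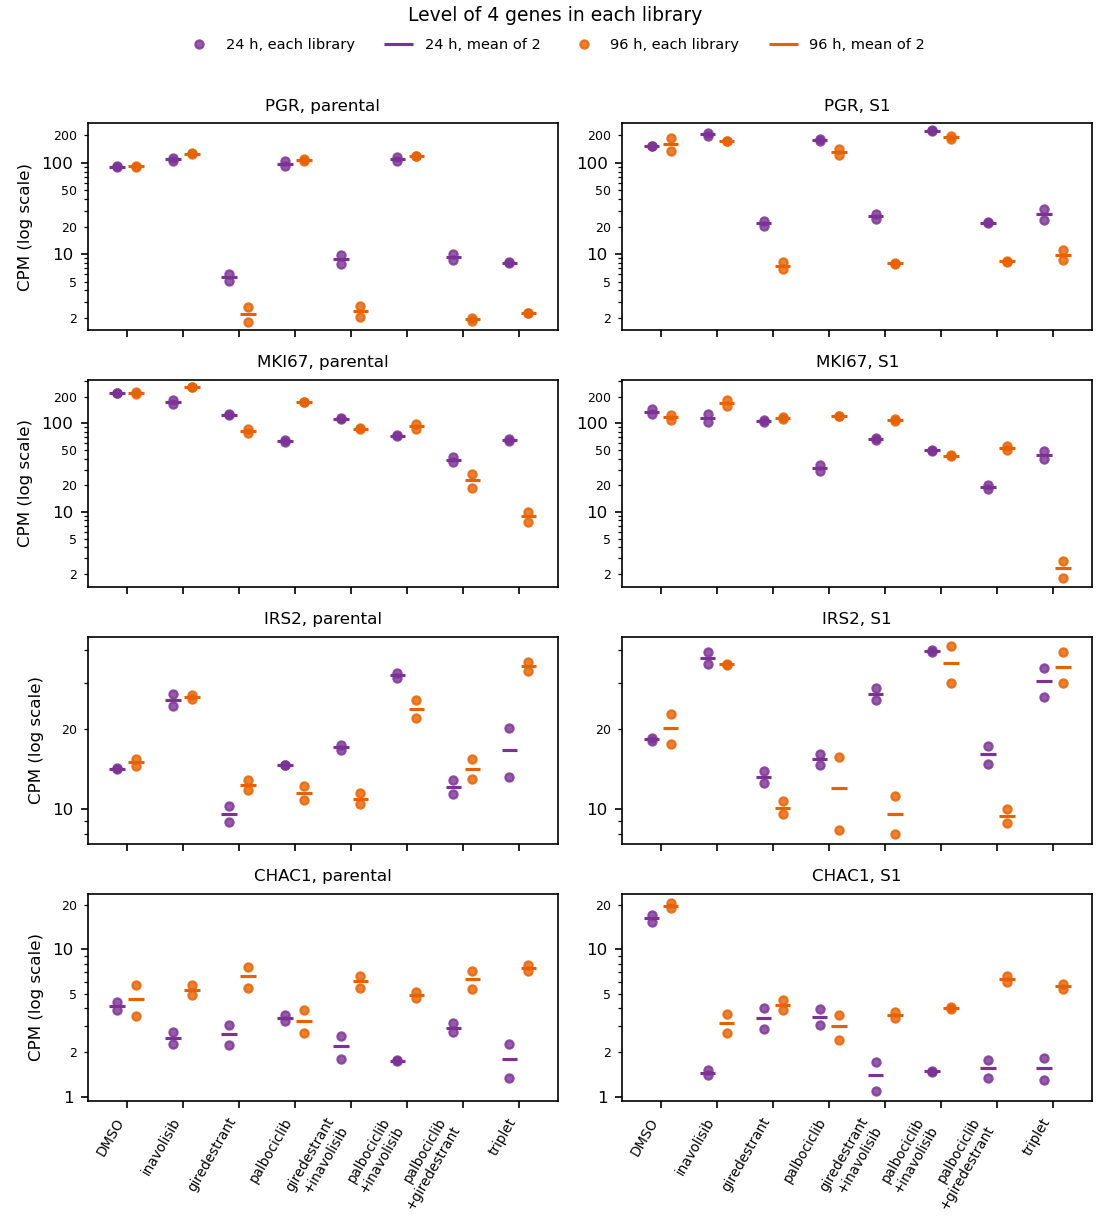
CPM of PGR, MKI67, IRS2 and CHAC1 in each library, on a log axis, by treatment and line. Points stand for libraries, bars for the mean of 2 libraries, purple for 24 h and orange for 96 h. In DMSO at 24 h PGR was at 91.0 CPM in parental cells and at 152 in S1, and it was lower in every group with giredestrant.

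Whether the lines respond differently was tested as the difference of the treatment effects, S1 minus parental. The lists were not tested for this difference. At 24 h SLC7A11 differed by -3.35 ± 0.50 with inavolisib and by -2.61 ± 0.46 with palbociclib, SLC7A5 by -2.33 ± 0.14 with inavolisib and NUPR1 by -2.52 ± 0.27 with palbociclib. At 96 h CHAC1 differed by -2.89 ± 0.32 with inavolisib and SLC7A11 by -2.76 ± 0.46 with palbociclib and -4.06 ± 0.48 with giredestrant. CRISP3, a secreted protein of exocrine glands, differed at 96 h by 3.14 ± 0.52 with inavolisib and by 3.27 ± 0.53 with palbociclib. DPYSL5, a neuronal phosphoprotein gene, differed by 1.98 ± 0.36 with palbociclib at 24 h. With giredestrant CEMIP, a hyaluronan-binding protein gene, differed by 2.50 ± 0.47 at 24 h. For MGP the difference was 5.07 ± 0.92 at 96 h, while FFAR2, a fatty acid receptor, differed by -5.80 ± 0.75. With the triplet at 96 h the kinetochore gene KNL1 differed by 3.12 ± 0.34, CALB2 by 7.29 ± 1.05 and the pregnancy glycoprotein PSG9 by -4.41 ± 0.39.

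At 24 h the tests found 117 genes for inavolisib (34 higher), 581 for giredestrant (336 higher), 567 for palbociclib (435 higher) and 920 for the triplet (547 higher). At 96 h they found 1411 (637 higher), 3706 (1652 higher), 1365 (629 higher) and 3810 (1552 higher). At 24 h leaving out 1 library moved the inavolisib count to between 56 (parental DMSO replicate 2) and 76 for 7 of the 8 libraries, all but S1 inavolisib replicate 1. The giredestrant count became 358 (parental DMSO replicate 1), 331 and 334 (replicate 2 of parental and S1 giredestrant). The palbociclib count fell to between 120 (parental palbociclib replicate 2) and 327 (S1 DMSO replicate 1) for 7 of 8. At 96 h the counts without S1 DMSO replicate 1 were 4891, 6478, 5470 and 6595 in the order of the drugs. The inavolisib count at 96 h became 845 without parental DMSO replicate 2, 851 and 747 without replicates 1 and 2 of parental inavolisib and 660 without replicate 1 of S1 inavolisib. For palbociclib at 96 h it became 575 and 819 (parental DMSO replicates 1 and 2), 565 (parental palbociclib replicate 2), 584 (S1 DMSO replicate 2), 462 and 3787 (S1 palbociclib replicates 1 and 2). Over the 20890 tested genes, which are not independent replicates, the effects in the 2 lines correlated (Pearson, 24 h and 96 h) at 0.18 and 0.13 for inavolisib, 0.40 and 0.46 for giredestrant, 0.15 and 0.11 for palbociclib. The values were 0.53 and 0.50 for giredestrant with inavolisib, 0.35 and 0.30 for palbociclib with inavolisib, 0.50 and 0.51 for palbociclib with giredestrant and 0.52 and 0.61 for the triplet. Spearman values in the same order of treatments were 0.38, 0.48, 0.20, 0.61, 0.48, 0.56 and 0.61 at 24 h. At 96 h they were 0.19, 0.43, 0.13, 0.45, 0.40, 0.50 and 0.58. Of genes called in both lines, 1170 of 1173 had the same direction for inavolisib at 24 h, 2475 of 2498 for giredestrant and 806 of 839 for palbociclib. The numbers were 557 of 617, 3943 of 4259 and 638 of 715 at 96 h.

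Pairs of drugs were tested for departure from the sum of their single effects on the log scale. The lists were not tested for this departure. In S1 the amino acid transporter gene SLC7A11 departed by 3.31 ± 0.51 for giredestrant with inavolisib and 3.16 ± 0.50 for palbociclib with inavolisib at 24 h. It departed by 3.43 ± 0.56 for palbociclib with giredestrant at 96 h, where CHAC1 departed by 3.31 ± 0.33. A departure above 0 is measured from the sum of the single effects and is not in itself a rise against DMSO. Inavolisib alone lowered SLC7A11 in S1 at 24 h, and palbociclib alone lowered CHAC1 at 96 h. The S1 DMSO libraries enter each departure, and whether their state set the level of ATF4 and amino acid genes stays open. With palbociclib and inavolisib in S1 at 96 h NDC80, a kinetochore gene, departed by -2.72 ± 0.45 and ANLN, which encodes the cytokinesis protein anillin, by -2.57 ± 0.31. With palbociclib and giredestrant in parental cells at 96 h KIF4A, a mitotic kinesin, departed by -1.97 ± 0.22 and MCM10 by -2.16 ± 0.27. In parental cells 9 (2 higher), 1 (1 higher) and 59 (44 higher) genes departed at 24 h for giredestrant with inavolisib, palbociclib with inavolisib and palbociclib with giredestrant. The numbers at 96 h were 491 (293 higher), 794 (467 higher) and 452 (181 higher). In S1 the counts were 137 (54 higher), 180 (120 higher) and 86 (42 higher) at 24 h and 1854 (1116 higher), 2098 (1214 higher) and 1300 (759 higher) at 96 h. Giredestrant with inavolisib differed from giredestrant alone in 0 and 5 genes at 96 h, and if those cells saw no inavolisib, its 491 and 1854 departures are the effect of inavolisib alone with the sign reversed. Leaving out 1 library moved the parental counts at 24 h to 0 to 11 for giredestrant with inavolisib, 0 to 2 for palbociclib with inavolisib and 0 (palbociclib replicate 2) to 90 (palbociclib replicate 1) for palbociclib with giredestrant. The lowest at 96 h were 185 (giredestrant replicate 1), 355 and 245 (replicate 1 of the pair), and the lowest in S1 at 24 h were 78, 96 and 24. In S1 at 96 h the counts were 5152, 6449 and 5616 without DMSO replicate 1, 919 without inavolisib replicate 1, 784 without DMSO replicate 2 and 350 without palbociclib replicate 1.

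Between 24 h and 96 h in DMSO, 0 genes changed in parental cells by edgeR, with 693 at an unadjusted p under 0.05 and 0 by DESeq2. In S1 13 changed (6 higher), with 348 by DESeq2. Without S1 DMSO replicate 1 at 96 h the S1 count was 5809, without replicate 2 it was 0, and without replicates 1 and 2 at 24 h it was 1 and 0. Whether a drug's effect differed between the times was tested as the effect at 96 h minus that at 24 h. The lists were not tested for this difference either. With palbociclib in parental cells EXO1, a repair exonuclease, differed by 2.76 ± 0.24 and CCNE2, cyclin E2, by 2.64 ± 0.41. In S1 the replication factor PCLAF differed by 3.45 ± 0.50 and NDC80 by 2.98 ± 0.46. With giredestrant the immunoglobulin superfamily gene IGSF1 differed by -5.46 ± 0.27 and GABBR2, a GABA receptor subunit, by 3.94 ± 0.64 in parental cells. In S1 the values were GREB1 at -3.08 ± 0.19 and APOD at 3.32 ± 0.23. The tests found 298 genes for inavolisib (148 higher), 2006 for giredestrant (1200 higher) and 759 for palbociclib (586 higher) in parental cells, and 580 (273 higher), 1429 (553 higher) and 2085 (958 higher) in S1. Without S1 DMSO replicate 1 at 96 h the S1 counts were 4207, 4940 and 6455. Without 1 of the other libraries they fell to as low as 233, 867 and 719 (S1 DMSO replicate 2 at 96 h for the last). In parental cells the lowest counts were 59 for inavolisib (DMSO replicate 2 at 96 h) and 469 for palbociclib (the same library).

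The 20 lists were tested in 42 comparisons, those of S1 with parental cells in DMSO, of each treatment with DMSO and of the triplet with each pair. Oestrogen-induced genes were called lower in 23 and higher in 4, and oestrogen-repressed genes higher in 37. E2F and replication genes were lower in 37 and higher in 2, and mitosis genes lower in 35 and higher in 2. Cholesterol synthesis was lower in 38 and higher in 1, fatty acid synthesis lower in 35 and higher in 1, and glycolysis and hypoxia lower in 18. FOXO and receptor feedback genes were higher in 31, p53 targets higher in 24 and lower in 3, and the amino acid and ATF4 list lower in 26 and higher in 6. Ribosome biogenesis genes were lower in 29 and higher in 2, MAPK output genes lower in 18 and higher in 3, and heat shock genes lower in 10. Interferon and antigen presentation genes were higher in 30 and lower in 4, of which 4 calls held with an estimated correlation, and lysosome genes higher in 29 and lower in 2, of which 7 held. Luminal genes were higher in 15, basal and mesenchymal genes higher in 6 and lower in 9 (the median had the other sign in 2), and secreted senescence factors higher in 7 and lower in 3. The test called mitochondrially encoded genes higher in 8 and lower in 1, of which 0 held. Markers of other cell types, with 10 of 19 genes measured, were called in 0 comparisons. With an estimated correlation the calls held in 21 comparisons for oestrogen-induced genes, 28 for oestrogen-repressed, 32 for E2F, 32 for mitosis, and 32 for cholesterol. They held in 22 for fatty acid synthesis, 13 for glycolysis, 22 for FOXO, 21 for p53, 27 for the ATF4 list, 22 for ribosome biogenesis, 12 for MAPK, 3 for heat shock, 5 for luminal, 12 for basal and 3 for senescence factors.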

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

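The counts of genes and the single genes given first in this part were picked out because a test of the difference itself passed at an adjusted p of 0.05. That test was an interaction in the 64-library edgeR fit. The patterns of inavolisib added to giredestrant, of the E2F list and of the ATF4 list were not picked by such a test. For these patterns the difference between times or lines was not tested. Some tests of explanations were chosen only after the result was seen. They were the direction shared by the lines under palbociclib and the ATF4 list under palbociclib at 96 h. The use of the 96 h palbociclib counts against a faded effect was chosen then too.

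At 24 h the responses of S1 and parental cells differed in 117 genes for inavolisib, 581 for giredestrant, 567 for palbociclib and 920 for the triplet. At 96 h the numbers were 1411, 3706, 1365 and 3810, and without S1 DMSO replicate 1 they were 4891, 6478, 5470 and 6595. Without the pair of libraries that stood apart they were 1375, 3329, 392 and 3542, so the palbociclib count fell and the other 3 moved little. Between 24 h and 96 h the response of parental cells changed in 298 genes for inavolisib, 2006 for giredestrant and 759 for palbociclib. In S1 the same tests gave 580, 1429 and 2085 genes, and without DMSO replicate 1 at 96 h 4207, 4940 and 6455. Without the pair of libraries that stood apart they gave 417, 1440 and 565, and without DMSO replicate 2 at 96 h palbociclib gave 719.

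Among the genes of the rule, the difference S1 minus parental at 24 h was highest for DPYSL5 (1.36) and lowest for SLC7A11 (-3.35) with inavolisib. DPYSL5 passed there at an adjusted p of 0.0413, did not pass without any 1 of the 8 libraries (log2 fold 1.22 to 1.46, adjusted p = 0.0614 to 0.227), and with the gene-body counts had 0.0514. With giredestrant it was 2.50 for CEMIP and -3.59 for INSYN1, with palbociclib 1.98 for DPYSL5 and -2.61 for SLC7A11, and with the triplet 2.73 for FOXN1 and -3.11 for INSYN1. At 96 h inavolisib gave 3.14 for CRISP3 and -2.89 for CHAC1, and giredestrant 5.07 for MGP and -5.80 for FFAR2. Palbociclib gave 3.27 for CRISP3 and -2.76 for SLC7A11, and the triplet 7.29 for CALB2 and -5.39 for FFAR2.

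Inavolisib added to giredestrant changed almost no genes at 96 h, although it changed many at 24 h and many at 96 h when added to palbociclib. The ratio of the median standard errors to those for palbociclib was 1.01 in parental cells and 0.98 in S1. Library number and depth thus did not lower the precision. The fit holds 1 spread per gene for all groups, so this ratio cannot show whether these libraries varied more than others. Lower precision from such a wider spread stays open. Fading of inavolisib in every combination is argued against by the 3143 and 5435 genes that changed at 96 h when it was added to palbociclib, with slopes of the 96 h on the 24 h values of 0.55 and 0.49. The bound of 0.5 written in advance was missed in S1, and the slopes with giredestrant were -0.01 and -0.01. Cells in these libraries that saw no inavolisib cannot be told apart from a true absence of effect: over the genes that inavolisib changed on top of palbociclib with giredestrant, the correlation was 0.13 in parental cells and 0.03 in S1, with a lowest value of -0.03 between single libraries, against 0.50 and 0.67 for inavolisib added to palbociclib.

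E2F and DNA replication genes lay near the DMSO level after 96 h of palbociclib in both lines. A slowing of the DMSO cells is argued against by the list from 24 h to 96 h in DMSO. There it moved by a median of 0.09 in parental cells and 0.17 in S1 (0.15 without replicate 2). With palbociclib its median rose by 1.69 and 1.45, and this difference between the times was not tested for the list. Of the 715 genes that passed in both lines, which share no library, 89.2% changed in the same direction. A difference between DMSO and palbociclib libraries other than the drug, if shared by the lines, could give this too. The shared direction therefore cannot decide whether the cells of these libraries saw palbociclib. A return of the cells to division and a loss of drug from the medium both stay open, and neither was tested.

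ATF4 and amino acid genes were lower in S1 under each of the 7 treatments at both times. A single unusual DMSO library is argued against: 4 of the 4 S1 DMSO libraries (5.31, 5.18, 5.20 and 5.18 as mean log2 CPM) lay above all 28 treated libraries (3.82 to 4.53). With palbociclib at 96 h the median of the ATF4 list was -0.95 (-0.83 without the pair of libraries) and that of the mitosis list 0.11 (-0.30). The direction of the mitosis list there depended on which DMSO library was left out, and both medians use the same DMSO libraries. These values therefore cannot decide whether the ATF4 list follows the rate of division. In parental cells DMSO libraries ran from 4.74 to 4.89 and treated ones from 4.12 to 4.99. Whether the drugs lowered the list or the S1 DMSO wells were in another state, in medium or density, stays open, since all 7 treatments share their DMSO libraries.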

How the results depend on the processing

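No paired analysis was possible because replicate numbers only follow the order of deposit. In this part I, G and P stand for inavolisib, giredestrant and palbociclib, GI, PI and PG for their pairs and PGI for the triplet. A count of genes that changed was called moved when it differed from the reported count by more than 1.5 times. The gene-body counts, the fit without the pair that stood apart, and inavolisib added to a single drug were chosen after seeing the data. Where no cause is given below, the cause was not tested.

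With the size factors of DESeq2, 0 of 78 counts moved. The stricter filter moved 2 of 78, to 15 for GI in parental cells at 24 h for the departure from the sum of 2 drugs and to 0 on G in S1 at 96 h for inavolisib added to a single drug, and the gene-body counts moved 1 of 78, to 3 in S1 between the times in DMSO. The Wald test of DESeq2 moved 13 of 78. It gave 251 for I at 24 h between the lines, 348 in S1 between the times in DMSO and 8 on G in S1 at 96 h for inavolisib added. For the times of a treatment its counts were 559 for I in parental cells, and 917 for I in S1. Departures from the sum of 2 drugs numbered 43 for GI, 15 for PI and 175 for PG in parental cells at 24 h, 748 for GI in parental cells at 96 h, 270 for GI, 300 for PI and 193 for PG in S1 at 24 h, and 1986 for PG in S1 at 96 h.

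No filter moved 13 of 78 counts. A drug added to the other pair gave 253 for P in parental cells at 24 h, and 171 for P in S1 at 24 h, the lines 2345 for P at 96 h and the times of a treatment 1169 for I in S1. Departures from the sum were 18 for GI, 10 for PI and 227 for PG in parental cells at 24 h, 141 for PG in S1 at 24 h, and 2177 for PG in S1 at 96 h. The times in DMSO gave 14 in parental cells and 1209 in S1, and inavolisib added to a single drug 20 on G in parental cells at 96 h, and 37 on G in S1 at 96 h.

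The fit over the libraries of the same line, which holds 32 in place of 64, moved 25 of 68 counts. Against DMSO it gave 1757 for I in parental cells at 96 h, and 2936 for P in S1 at 96 h, and for a drug added to the other pair 2098 for I and 204 for P in parental cells at 24 h. Departures from the sum became 17 for GI, 2 for PI and 172 for PG in parental cells at 24 h, 913 for GI, 1255 for PI and 793 for PG in parental cells at 96 h, 84 for GI, 97 for PI and 49 for PG in S1 at 24 h, and 1213 for GI, 1025 for PI and 528 for PG in S1 at 96 h. The times in DMSO gave 3 in parental cells and 0 in S1, the times of a treatment 657 for I and 1241 for P in parental cells, and 209 for I and 908 for P in S1, and inavolisib added 1777 on G and 2311 on P in parental cells at 24 h, and 1 on G in S1 at 96 h. The fit over the same time moved 6 of 10 counts between the lines, to 398 for I, 1343 for G, 1706 for P and 1799 for PGI at 24 h, and 586 for I and 345 for P at 96 h.

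Without S1 DMSO replicate 2 and S1 palbociclib replicate 1 at 96 h, 32 of 78 counts moved, also in comparisons that use neither library. This fit tested 21864 genes in place of 20890 and estimated the spread anew, and the cause of the moves was not tested. Against DMSO the counts were 2916 for I and 3083 for P in parental cells at 24 h, 1911 for I and 2887 for P in parental cells at 96 h, and 998 for P in S1 at 96 h, which sets 1 library against 1 and takes the spread from the other groups. A drug added to the other pair changed 2321 for I and 243 for P in parental cells at 24 h, 2487 for I in parental cells at 96 h, and 172 for P in S1 at 24 h. Between the lines they were 362 for I, 1161 for G, 1450 for P and 1630 for PGI at 24 h, and 392 for P at 96 h, and departures from the sum 30 for GI, 13 for PI and 644 for PG in parental cells at 24 h, 1072 for GI, 1456 for PI and 894 for PG in parental cells at 96 h, 377 for GI, 423 for PI and 251 for PG in S1 at 24 h, and 779 for PI and 313 for PG in S1 at 96 h. The times in DMSO gave 0 in S1, the times of a treatment 817 for I, 3050 for G and 1497 for P in parental cells, and 565 for P in S1, and inavolisib added 1928 on G and 2504 on P in parental cells at 24 h.

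Leaving out each library of a comparison in turn moved 213 of 416 counts. A fit with a lone library in a group has a larger standard error by construction, which lowers a count, and the cause of the rises was not tested. The ranges of the comparisons with such a value were, against DMSO, 684 to 1026 for I, 871 to 1394 for P and 2692 to 3494 for PI in parental cells at 24 h, 490 to 607 for I and 829 to 1135 for P in parental cells at 96 h, 1825 to 2230 for I, 2381 to 2983 for G and 1187 to 1247 for P in S1 at 24 h, and 2500 to 7227 for I and 1342 to 7631 for P in S1 at 96 h. For a drug added to the other pair they were 447 to 689 for I, 1792 to 2240 for G and 45 to 92 for P in parental cells at 24 h, 745 to 850 for I and 1598 to 1694 for P in parental cells at 96 h, 1617 to 1884 for I, 1342 to 1630 for G and 14 to 76 for P in S1 at 24 h, and 2891 to 3134 for I in S1 at 96 h. Between the lines the counts ran 56 to 113 for I, 331 to 536 for G and 120 to 508 for P at 24 h, and 660 to 4891 for I, 2768 to 6478 for G, 462 to 5470 for P and 2801 to 6595 for PGI at 96 h. Departures from the sum ran over 0 to 11 for GI, 0 to 2 for PI and 0 to 90 for PG in parental cells at 24 h, 185 to 723 for GI, 355 to 815 for PI and 245 to 493 for PG in parental cells at 96 h, 78 to 107 for GI, 96 to 137 for PI and 24 to 121 for PG in S1 at 24 h, and 919 to 5152 for GI, 784 to 6449 for PI and 350 to 5616 for PG in S1 at 96 h. The times in DMSO gave 0 to 5809 in S1 and the times of a treatment 59 to 263 for I and 469 to 665 for P in parental cells, and 233 to 4207 for I, 867 to 4940 for G and 719 to 6455 for P in S1. For inavolisib added to a single drug they were 447 to 998 on G and 356 to 1215 on P in parental cells at 24 h, 0 to 166 on G and 1516 to 2770 on P in parental cells at 96 h, 2060 to 2264 on G and 1942 to 2237 on P in S1 at 24 h, and 0 to 2 on G and 3126 to 6334 on P in S1 at 96 h.

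The correlation of the responses of the lines over genes past the threshold in either line was, at 24 h, 0.44 for I, 0.63 for G, 0.55 for P, 0.67 for GI, 0.62 for PI, 0.72 for PG and 0.69 for PGI, and at 96 h 0.25, 0.59, 0.24, 0.60, 0.45, 0.62 and 0.70. These differ by construction from those over all genes, since genes are chosen for the size of their change. Over all genes, the correlation without the pair of libraries was 0.33 for G, 0.13 for P, 0.47 for GI, 0.31 for PI, 0.44 for PG and 0.47 for PGI at 24 h, and 0.40, 0.08, 0.44, 0.26, 0.47 and 0.57 at 96 h. With all libraries these were 0.40, 0.15, 0.53, 0.35, 0.50 and 0.52 at 24 h, and 0.46, 0.11, 0.50, 0.30, 0.51 and 0.61 at 96 h.

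Camera with an estimated correlation called 318 of 840 list tests, with 659 on the same side of the threshold and 181 lost. Without a library, 3176 of 3360 list results stayed on their side, 126 were lost and 53 were gained. Another 5 changed direction with either result past the threshold, all without S1 DMSO replicate 2 at 96 h. These had adjusted p of 0.888 for mitochondrially encoded genes between the lines in DMSO at 96 h (4.84e-09 to 0.888 over all libraries left out). The same list had 0.852 with GI (3.6e-11 to 0.852) and 0.863 with PG (7.35e-11 to 0.863) in S1 at 96 h. Mitosis genes had 0.0201 with I (0.0194 to 0.972) and 0.012 with P (0.012 to 0.3) in S1 at 96 h.

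For the genes named in the text, 0 fold changes changed direction with either value past the threshold. Changes of sign between values that did not pass were not counted. The side of the threshold was kept by 271 of 272 with the size factors of DESeq2 (1 gained and 0 lost), 269 of 270 with its Wald test (1 gained and 0 lost), 262 of 272 with no filter (7 gained and 3 lost), 266 of 268 with the stricter filter (2 gained and 0 lost) and 263 of 268 with the gene-body counts (3 gained and 2 lost). It was also kept by 209 of 216 in the fit over a line (3 gained and 4 lost), 51 of 56 in the fit over a time (4 gained and 1 lost), 254 of 272 without the pair of libraries (14 gained and 4 lost) and 1182 of 1244 without a library in turn (13 gained and 49 lost). Of genes past the threshold, the share that were higher moved by more than 10 points for GI in parental cells at 24 h (22.2% to 10% with the size factors of DESeq2), for PI in parental cells at 24 h (100% to 46.7% with DESeq2) and at 96 h (58.8% to 48.6% with the size factors), and for PI in S1 at 24 h (66.7% to 54.3% with DESeq2), all in departures from the sum.

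What depth limits was not tested by drawing fewer reads, and genes too low for the filter gave no result. In the self-test an interaction of 1.5 times was found for 20.1% of the planted genes.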

Other observations

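The list tests in this part were planned. The comparisons with GC content, transcript length and the gene-body counts were chosen only after the data were seen. In parental cells at 24 h, interferon and antigen presentation genes rose in 9 of 28 with 0 lower when inavolisib was added to palbociclib with giredestrant (14 and 0 adjusted over the list alone, median 0.52, adjusted p = 6.1e-10, or 0.0721 with an estimated correlation). At 96 h the same step lowered 16 and raised 0 (18 and 0 adjusted over the list alone, median -0.59, adjusted p = 1.69e-16, or 0.0173). Palbociclib added to giredestrant with inavolisib lowered 20 and raised 0 in parental cells at 96 h (21 and 0, median -0.84, adjusted p = 3.07e-16, or 0.0213). That reference pair differed from giredestrant alone in 0 genes at 96 h, so whether the step added palbociclib alone or inavolisib as well is open. In S1 at 96 h the steps gave 3 higher and 2 lower for inavolisib (3 and 2 adjusted over the list alone, median 0.05, adjusted p = 0.704) and 6 higher and 1 lower for palbociclib (6 and 1, median 0.14, adjusted p = 0.222). The difference between the lines in this list was not tested.

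Within a group, the log ratio of the 2 libraries was compared with GC content and gene length over 11383 genes by Spearman correlation. For S1 in DMSO at 96 h the values were 0.44 in size for GC and 0.20 for length, and for S1 in palbociclib at 96 h 0.26 and 0.38. The medians of the sizes over the 32 groups were 0.26 and 0.16, and the largest for GC was 0.69, in parental cells with giredestrant at 96 h. The largest for length was the 0.38 of S1 in palbociclib at 96 h. The pairs had a dispersion of 170.5 and 60.65 as chi-square per degree of freedom in S1 at 96 h in DMSO and palbociclib. The second counting over the gene body gave a median of 1.089 times the count of the series table over 12903 genes, and 429 genes had under 50% of it.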
